A study of Mus musculus with 283 samples.

How the data were processed

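Per the labels' protocols, tumours were grown orthotopically in syngeneic mice and mice were assigned to arms at a tumour diameter of 5 mm. The labels repeat this text for every sample, primary tumours and glands included, and whether it holds for those is not known. They also state that antibodies were injected intraperitoneally in 100 ul, with 125 ug of anti-CTLA4 and 10 mg per kg of anti-PD1. RNA was extracted with Qiagen kits and libraries were made with the Illumina TruSeq mRNA kit, per the labels' protocols. They were read from both ends for 50 bases on Illumina HiSeq instruments, per the same protocols. Per the submitters' processing notes, STAR, SAMtools, Picard and Salmon were used with the mouse build mm10. Their order and settings, their versions and the gene annotation are not given in the sources used here.

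The deposited values are a gene-level signal that the authors scaled by the upper quartile, per the file headers. In the tumour table the upper quartile of the genes above 0 was 2048.974 in each library, and in the cell line table it was 1000. The worth of 1 read was estimated from the steps between small values, which gave the estimated reads per library. Within a tolerance of 0.01 reads, 29.0 to 83.0% of the values of a tumour library were whole reads, with a median of 70.8%. In the cultured lines these shares were 67.5 to 71.0%. The values were therefore treated as normalized signal on a linear scale, and no test for counts was used.

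There were 45724 gene entries for the tumours and 47480 for the cell lines. Entries whose names had turned into dates, 39 and 27, were left out because their genes could not be told with certainty. A further 28 entries of 14 repeated symbols were left out of the tumour table, and 45657 and 47453 were kept. The entries left out held 0.21 to 0.457% of the signal of a tumour library. Symbols were matched to the mouse names table, where 45076 and 45187 of those kept were found, and the list symbol Ca9 was read as Car9. The tumour table was joined from 2 parts of 145 and 119 libraries. Positions in GRCm38 (mm10) were taken from the GENCODE annotation for 400 of 401 symbols looked up. The exome libraries were not analysed here.

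The 2 libraries of 1 untreated KPB25L mouse at 7 days, of which the labels mark 1 as a repeat, were averaged to 1 sample. Signal was put on a log2 scale after adding 1. Genes above 0 in at least 4 fitted samples were ranked by mean, and the upper 66.7% were tested, which gave 20848 genes in the tumour comparisons. Linear models with 1 mean per group of model, time and arm were fitted with limma, with moderated variances that follow the mean. All 47 groups shared 1 spread with 145 residual degrees of freedom. Contrasts over several models gave each model the same weight. P-values were adjusted by Benjamini-Hochberg over the genes tested and called at 0.05. The difference between sensitive and resistant models, and that between a derivative and T11, was tested as an interaction. The class comparison of untreated tumours used the means of 12 models as replicates. End-stage tumours of 4 of the models of unknown response and the 9 glands were fitted together, with glands of the BALB/c and FVB strains weighted equally. P-values measure spread between mice, pooled over the groups of a fit, since the labels give each library a mouse number. Those of the class comparison measure spread between models. The labels give mouse numbers DH1012 to DH1015 both to T11-UV at 7 days and to KPB25L-UV at end stage, and these libraries were kept.

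Of 41 gene lists of cell types and pathways fixed before the data were examined, 40 had at least 3 tested members. The list of mitochondrially encoded genes did not, and it was not tested. Lists were tested with fry of limma, adjusted over the lists of 1 comparison, and with camera with an estimated correlation between members as the alternative. Members were also adjusted over the list alone. The cultured lines had 1 library each and were compared by value only, with the median of a list set against 10000 random lists of the same size matched on mean.

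The genes named in the text followed a rule fixed before the data were examined, as were the comparisons, tests and lists. It took up to 6 genes per direction with the largest difference among called genes with a mean above the median and, for averaged models, the same sign in each model. It passed over predicted genes and receptor segments. It added up to 3 called members with the smallest adjusted p from each called list, and a panel of 17 genes of T cells, B cells, checkpoints and interferon response. Some of the genes it took are not reported here. For glands it took list members only. For cultured lines it took Apobec3, the panel and the 2 members of each list with the largest difference. The marker transcripts of the 2 parental lines and the strain transcripts Gvin1 and Ang5 were chosen after the values were seen.

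Alternatives planned beforehand were a pseudocount of 10, no filter on the mean, median-of-ratios rescaling, fits of only the groups of a comparison, array weights of limma, the flow cell of the labels as a term, both libraries of the repeated mouse kept apart and each replicate of groups of up to 5 libraries left out in turn. The class comparison was also fitted with single tumours and the model as a random effect, with BALB/c models only and without each model. Added after seeing the data were the flow cell of the file headers as a term, the part of the joined table as a term, log2 estimated reads as a covariate, models with both arms on 1 flow cell only, fits without 6 libraries labelled KPB25L-UV that held T11 transcripts, and list tests without 1 KPB25L-UV, 1 KPB25L-Apobec or 1 T11-Apobec library. File headers named 25 flow cells, with none for 19 libraries, and labels named 20, with none for 114. The fits were made in R 4.3.3 with limma 3.58.1, and tables and plots in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

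The fits were tried on simulated values built from the real libraries with 100 genes changed by 1 log2 and 100 by 2. The noise was normal with 1 spread per gene for all groups of a fit. The shares recovered therefore do not reflect the depth or spread of single models. In the 7-day comparison of sensitive models, 64% and 97% were recovered. In T11 at 7 days 36% and 70% were recovered, and in KPB25L 17% and 57%. At end stage in sensitive models 69% and 99% were recovered, and in resistant models 76% and 95%. In the class comparison over 17920 genes 5% and 38% were recovered.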

Results

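The series held 283 samples from mice and mouse cell lines, of which 270 were RNA-seq libraries and 13 were exome libraries, which were not analysed here. The RNA-seq libraries comprised 264 from tumours or normal mammary glands and 6 from cultured lines. Per the labels, tumours were grown orthotopically in syngeneic mice, which entered the study at a tumour diameter of 5 mm, a text that the labels repeat for every sample, glands included. Treated mice received antibodies against the checkpoint receptors PD1 and CTLA4, together called therapy below. Tumours were taken after 3 days, after 7 days or at end stage. The labels class the tumour models by response, which gave 107 libraries of sensitive models, 86 of resistant models and 62 of models of unknown response, beside 9 normal glands. T11 and KPB25L were 2 parental mammary tumour lines, and the names ending in UV and Apobec mark derivatives of them. T11 was classed as resistant, and its derivatives T11-UV and T11-Apobec as sensitive. KPB25L and its derivatives were classed as sensitive.

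The tumour comparisons used 192 libraries in 47 groups. The 7-day comparison of sensitive models held 18 treated and 15 untreated tumours of 4 models, and 4 treated and 4 untreated T11 tumours stood for the resistant class. At 3 days there were 15 treated and 17 untreated tumours of sensitive models, and 14 and 11 of resistant models. At end stage there were 16 and 20 of sensitive models, and 13 and 18 of resistant models. Each tumour library held an estimated 3.47 to 149.56 M reads, with a median of 51.4 M, and 16390 to 25883 genes above 0. The 6 cultured lines held an estimated 36.21 to 76.84 M reads. Values are the deposited upper-quartile normalized signal on a log2 scale after adding 1. Differences are given in log2 units ± SE from limma with Benjamini-Hochberg adjusted p, or for gene lists as the mean over members ± SD over members. For list members the count called over all genes is given, with the count adjusted over the list alone ("alone") where it differs. The labels give the libraries of a group separate mouse numbers, apart from 1 mouse with 2 libraries, which were averaged. The p-values therefore measure spread between mice, pooled over all groups of a fit and not only those compared. In the class comparison they measure spread between models.

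The lines were told apart by 50 marker transcripts each, those with the largest gap between untreated T11 and KPB25L tumours at 3 days. These 2 groups therefore separate by construction. Some markers, such as Klra4, also differ between glands of the 2 strains. T11 markers averaged 6.85 to 9.29 in the 74 libraries labelled T11, T11-UV or T11-Apobec and 1.75 to 4.23 in the 32 labelled KPB25L or KPB25L-Apobec. Of the 27 libraries labelled KPB25L-UV, 21 had T11 marker means of 1.62 to 3.28 and 6 had means of 6.22 to 8.35. At 7 days these 6 included untreated replicates 3 and 4 and treated replicates 1 and 5. They also included 1 untreated library at 3 days and 1 at end stage. Counts that used these libraries were therefore repeated without the 6.

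**Figure D1:**
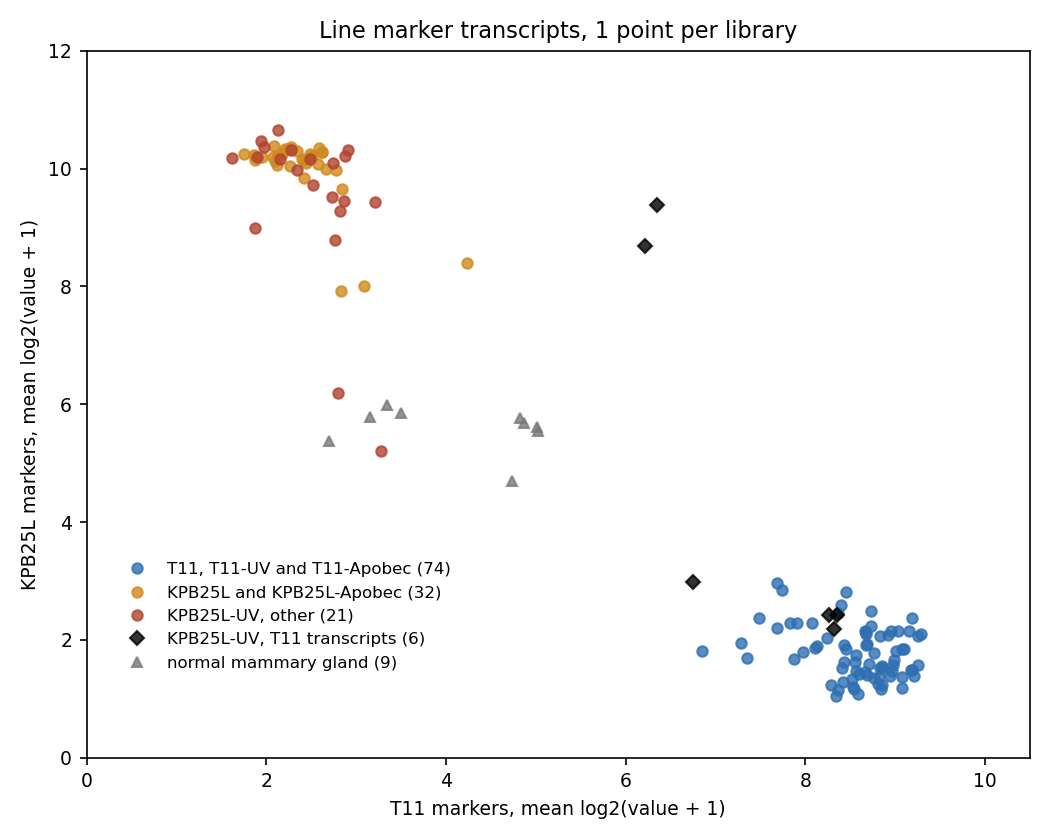
Each point is 1 library, with the mean log2 signal of 50 KPB25L marker genes on one axis and of 50 T11 marker genes on the other, for 74 T11-labelled libraries, 32 labelled KPB25L or KPB25L-Apobec, 21 and 6 labelled KPB25L-UV, and 9 normal glands. The 6 KPB25L-UV libraries lie at T11 marker means of 6.22 to 8.35, above the 3.28 reached by the other 21.

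After 7 days of therapy, T cell and cytotoxic genes rose in the sensitive models. The T cell list averaged 2.24 ± 0.438 log2 higher in treated tumours, and 16 of its 16 members rose. The CD8 and cytotoxicity list rose by 2.55 ± 0.59 with 14 of 14 members. Cd8a, the CD8 co-receptor chain, rose by 2.81 ± 0.49 (adjusted p = 2.7e-06), and the killing enzyme Gzmb rose by 2.81 ± 0.53. The cytokine gene Ifng rose by 3.15 ± 0.55 (adjusted p = 2.69e-06). Lat, a signalling adaptor of the T cell receptor, rose by 2.72 ± 0.32 (adjusted p = 3.55e-11). All 4 of these genes were higher in 4 of 4 models. The antibody targets moved too, with Pdcd1 higher by 2.47 ± 0.36 and Ctla4 by 2.22 ± 0.37. Cd274, which encodes the PD1 ligand, rose by 2.05 ± 0.34, and the other ligand gene, Pdcd1lg2, rose by 3.96 ± 0.54 (adjusted p = 4.79e-09).

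Several other single genes also rose in all 4 sensitive models at 7 days. Slc7a2, an arginine transporter, rose by 2.83 ± 0.35 (adjusted p = 1.17e-10), with a range of 1.01 to 4.69 across models. Nos2, which makes nitric oxide from arginine, rose by 2.57 ± 0.4 (adjusted p = 2.02e-07). The chemokine genes Ccl8 and Ccl6 rose by 2.69 ± 0.46 and 2.65 ± 0.37, and the acute-phase gene Saa3 rose by 2.67 ± 0.53. Among the genes that fell, the collagen gene Col11a1 dropped by 1.81 ± 0.36 (adjusted p = 2.63e-05), the actin-binding gene Palld by 1.78 ± 0.39 and Irs1, an insulin receptor substrate, by 1.77 ± 0.33. Rbpsuh-rs3 dropped by 2.08 ± 0.53, but it is a related sequence of another gene and its reads are uncertain. In total 3233 genes were higher and 4426 lower, of 20848 tested, and 1920 changed by over 2-fold. The count was 7309 without the 6 KPB25L-UV libraries. In GRCm38, Slc7a2 lies on chromosome 8 from 40862396 to 40922308, Nos2 on chromosome 11 from 78920787 to 78960254 and Cd8a on chromosome 6 from 71373427 to 71379173.

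**Figure D2:**
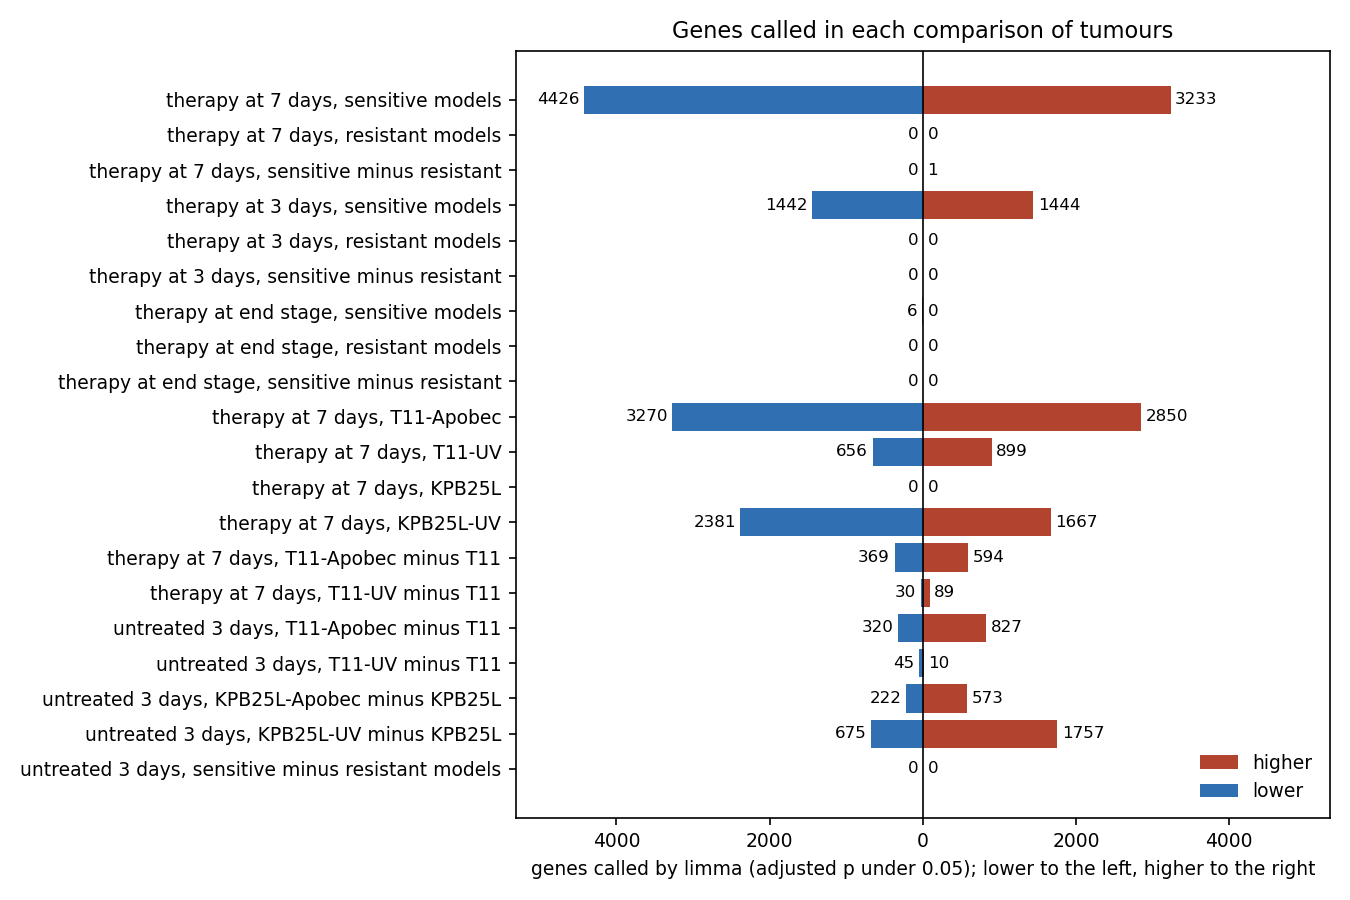
Bars give the number of genes with adjusted p under 0.05 in each tumour comparison, higher on one side and lower on the other. The 7-day comparison of sensitive models has 3233 higher and 4426 lower, and the same comparison in resistant models has 0.

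Of the 40 lists fixed beforehand, 23 rose and 2 fell in sensitive models at 7 days by fry, which tests whether the members move on balance one way and not whether they move more than other genes. With camera and an estimated correlation, 8 were higher. The T cell and CD8 lists and the checkpoint list (1.52 ± 1.01, 10 of 13 members, 12 adjusted over the list alone) each had adjusted p = 0.0395 with an estimated correlation. That p was 0.0497 for the T follicular helper list (1.3, 8 of 12, 9 adjusted over the list alone), the CD4 helper list (1.56, 7 of 10, 8 alone), the regulatory T cell list (1.39, 8 of 10, 8 alone), the T cell receptor variable genes (1.49, 8 of 9, 8 alone) and the cross-presenting dendritic cell list (0.922, 6 of 9, 8 alone). Tbx21, a regulator of helper T cells, rose by 2.57 ± 0.37, Icos by 2.32 and Foxp3 by 1.04 ± 0.24 (adjusted p = 0.000306). Batf3, needed for cross-presenting dendritic cells, rose by 1.71. Of the panel genes, Cxcr5 was at 0.98 ± 0.41 (adjusted p = 0.0515) and Bcl6 at 0.03 (adjusted p = 0.899).

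The remaining fry calls at 7 days did not hold with an estimated correlation, and the adjusted p given here is that one. The interferon gamma response rose by 1.52 ± 0.649 with 21 of 22 members (p = 0.106). Its members Ubd and Socs1 rose by 3.88 ± 0.66 and 1.69 ± 0.29. MHC class I presentation rose by 1.17 ± 0.288 with 15 of 15 members (p = 0.0894) and class II by 1.36 with 9 of 11 (10 alone, p = 0.0894). The peptide-loading gene Tapbp rose by 0.95 ± 0.15 and H2-Ab1 by 1.84 ± 0.32. Alternatively activated macrophage genes rose by 1.89 ± 2 with 6 of 11 members (p = 0.0894), and Chil3, a chitinase-like gene, rose by 5.71 ± 0.76 (adjusted p = 1.79e-09 by limma). General macrophage genes rose by 0.665 with 9 of 13 (11 alone, p = 0.0894), NK genes by 1.52 with 7 of 9 (8 alone, p = 0.0894) and the second dendritic cell list by 1.27 with 7 of 10 higher and 1 lower (8 and 1 alone, p = 0.0786). The B cell list rose by 0.992 with 8 of 15 (10 alone, p = 0.29), and Cd22, a B cell receptor regulator, rose by 1.82 ± 0.29. Plasma cell genes rose by 1.65 with 10 of 16 (11 alone, p = 0.0894), with Igha at 2.43 ± 0.49, and immunoglobulin variable genes by 1.45 with 2 of 4 (3 alone, p = 0.294). Lymphoid tissue genes rose by 1.19 with 8 of 12 (9 alone, p = 0.106) and chemokines by 1.15 with 9 of 14 (p = 0.109). Plasmacytoid dendritic cell genes rose by 0.639 with 3 of 8 higher and 2 lower (5 and 2 alone, p = 0.401), mast cell genes by 0.733 with 2 of 10 (0 alone, p = 0.456, and 0.684, not called by fry, without KPB25L-UV treated replicate 2) and p53 targets by 0.212 with 6 of 12 higher and 1 lower (p = 0.14).

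Cell cycle genes fell on average in sensitive models at 7 days, by 0.519 ± 0.24 with 17 of 20 members lower (adjusted p = 0.244 with an estimated correlation). By model the list was at -1.1 in KPB25L-UV, -0.69 in T11-Apobec, -0.32 in T11-UV and 0.04 in KPB25L. The mitotic cyclin genes Ccnb1 and Ccnb2 dropped by 0.9 ± 0.17 and 0.68 ± 0.13. Mesenchymal genes fell by 0.31 with 4 of 14 members (adjusted p = 0.465 with an estimated correlation), and Fn1, a matrix protein gene, dropped by 0.88 ± 0.23. The mesenchymal list was at -0.8 in KPB25L-UV, where both arms held libraries with T11 transcripts. Those transcripts and therapy were not told apart for this list there. The other lists were not called by fry. Among immune-related lists these were germinal centre (0.259), neutrophil (0.327) and type I interferon (0.56). Among epithelial lists they were luminal (0.218), claudins (0.626), milk protein (0.73), hair follicle (0.515) and basal epithelium, whose mean was 0.214 and median -0.041. In KPB25L-UV, claudin and basal genes fell once the libraries with T11 transcripts were left out, as given below. The stromal lists gave fibroblast (-0.223), endothelium (0.076), adipocyte (0.478) and skeletal muscle (-0.952). Erythroid (0.616), hypoxia (0.1) and immediate early genes (-0.062) completed the set.

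In resistant T11 tumours at 7 days, limma called 0 genes, with 61 at an unadjusted p under 0.05, and fry called 0 lists. In treated T11 tumours the T cell list was 0.465 higher and the CD8 list was at -0.028. Cd8a was 4.46 ± 0.6 (SD, n = 4) in treated and 3.99 ± 1.16 (SD, n = 4) in untreated T11 tumours. Gzmb was at -0.42 ± 1.06. The direct test of sensitive against resistant models called 3 lists. The CD8 list differed by 2.57 ± 0.798 (0 of 14 members called, 12 adjusted over the list alone), the checkpoint list by 1.38 (4 of 13 alone) and the T cell receptor variable genes by 1.53 (5 of 9 alone). Each had adjusted p = 0.0859 with an estimated correlation. For the T cell list the difference was 1.78 (adjusted p = 0.0514). The single gene called was Creg1, which encodes a secreted glycoprotein, at 1.46 ± 0.29 (adjusted p = 0.0231), with 1892 genes at an unadjusted p under 0.05. It lies on chromosome 1 from 165763746 to 165775308 in GRCm38. The resistant side rested on 1 model with 4 tumours per arm, and the count ran from 0 to 27 over the omission of single libraries, with 27 without T11-Apobec treated replicate 2 and 18 of 35 omissions moving it by over 1.5 times. The count was also higher with either flow cell term and with only models whose arms shared 1 flow cell, as given in the part on processing.

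**Figure D3:**
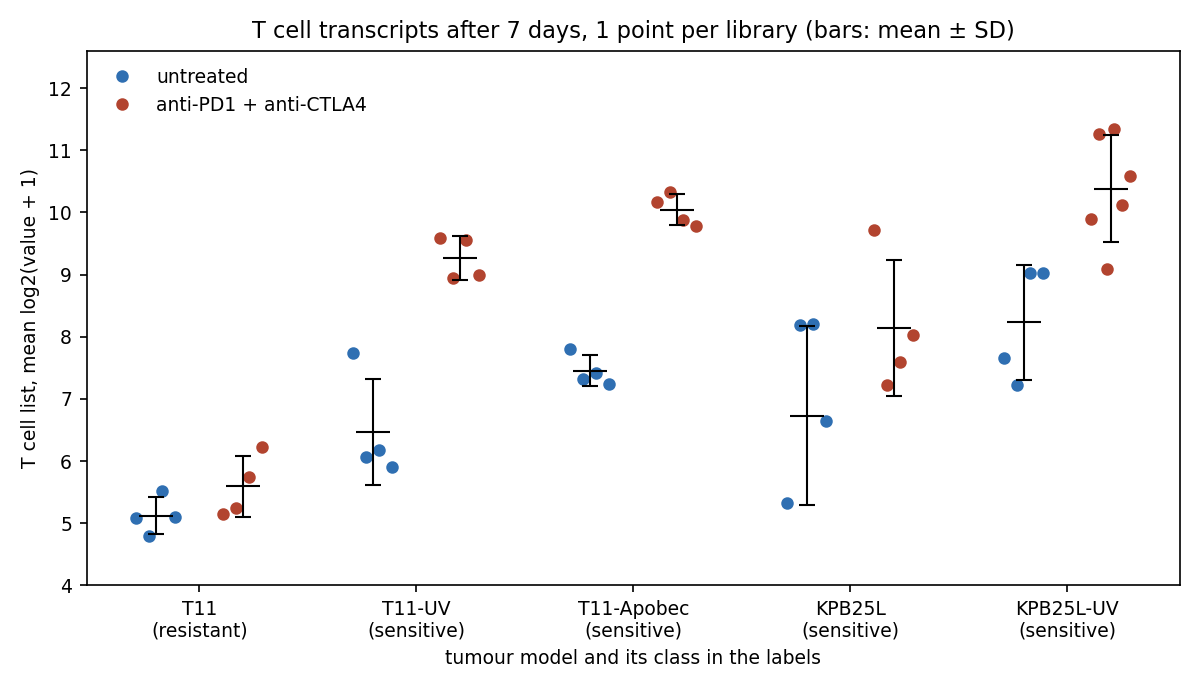
Each point is the mean log2 signal of the T cell list in 1 library at 7 days, untreated and treated, in 5 models, with bars for mean and SD. Treated T11-Apobec tumours average 10.04 against 7.45 untreated, and treated T11 tumours 5.59 against 5.12, and the 2 untreated KPB25L libraries of 1 mouse count as 1.

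T11-Apobec gave more calls than the other 4 models tested singly at 7 days, with 2850 genes higher and 3270 lower in 4 treated against 4 untreated tumours. Its T cell list went from 7.45 ± 0.25 to 10.04 ± 0.25 (SD, n = 4 each), a rise of 2.59 with 15 of 16 members (adjusted p = 0.207 with an estimated correlation, as for the next lists unless given). Nos2 rose by 5.69 ± 0.8 (adjusted p = 2.85e-08), the elastase gene Mmp12 by 4.7 ± 0.87 and Slc7a2 by 4.69 ± 0.7. Alternatively activated macrophage genes rose by 2.96 with 6 of 11 members (8 alone), and macrophage genes by 1 with 9 of 13. Pdcd1lg2 rose by 6.01 ± 1.09 and Cd274 by 3.15 ± 0.67. The checkpoint list rose by 2.17 with 8 of 13. Gzmb rose by 3.34 ± 1.06 (adjusted p = 0.0111), while Cd8a was at 2.31 ± 0.98 (adjusted p = 0.0634). Apobec3 was at 0.23 ± 0.22 (adjusted p = 0.468). p53 targets rose by 0.632 with 6 of 12, and the cell death gene Bax rose by 1.49 ± 0.25 (adjusted p = 3.12e-06) and the cell cycle inhibitor gene Cdkn1a by 2.1 ± 0.45. Cell cycle genes fell by 0.694 with 10 of 20 (11 alone, adjusted p = 0.476 with an estimated correlation), and Mki67 dropped by 1.52 ± 0.33. Fibroblast genes fell by 0.8 with 7 of 15 lower and 1 higher (9 and 1 alone, adjusted p = 0.509 with an estimated correlation), and Col11a1 dropped by 4.21 ± 0.71. T11 line markers were also lower, with a median of -0.692 and 12 of 49 called lower, so a smaller share of tumour cells was not told apart from these falls. Without T11-Apobec treated replicate 1 the count was 2605.

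T11-UV differed at 7 days in 1555 genes, 899 higher and 656 lower, and 12 of its 16 fry lists held with an estimated correlation. The CD8 list rose by 3.54 ± 1.19 with 12 of 14 members (13 alone, adjusted p = 0.00654 with an estimated correlation), and Cd8a went from 6.29 ± 1.12 to 10.28 ± 0.26 (SD, n = 4 each). Gzmb rose by 4.8 ± 1.06 and the pore-forming gene Prf1 by 4.98 ± 1.06. MHC class II presentation rose by 2.86 ± 0.635 with 11 of 11 members (adjusted p = 0.00654 with an estimated correlation), and Ciita, its master regulator, rose by 3.9 ± 0.68 (adjusted p = 2.2e-05). The interferon gamma response rose by 2.73 with 18 of 22 (21 alone, adjusted p = 0.0158 with an estimated correlation), and its guanylate-binding gene Gbp4, which has close paralogs, by 3.96 ± 0.85. Cross-presenting dendritic cell genes rose by 1.73 with 6 of 9 (8 alone), and Clec9a, a receptor of those cells, rose by 3.37 ± 0.54 (adjusted p = 6.01e-06). The complement gene C1s1 rose by 4.18 ± 0.53 (adjusted p = 2.81e-09), and Fcrls, a myeloid receptor gene, dropped by 4.22 ± 0.72. The median of all genes was -0.121, and after rescaling the split was 1141 higher and 521 lower. The 2 arms lay on different flow cells by the file headers, so flow cell and therapy cannot be told apart within this model, and with the header flow cell as a term the count was 8. Leaving out untreated replicate 3 gave 793 calls, untreated replicate 4 gave 1023 and treated replicate 1 gave 936. Of 35 splits of these libraries, the real one included, 6 called as many genes, so chance was not made unlikely.

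KPB25L-UV gave 1667 genes higher and 2381 lower at 7 days in 6 treated against 4 untreated libraries, of which 2 and 2 held T11 transcripts. The T cell list rose by 2.15 ± 0.38 with 15 of 16 members (16 alone), and Lat rose by 2.66 ± 0.59. The B cell list rose by 1.81 with 7 of 15 (12 alone), and the plasma cell list by 2.11 with 4 of 16 (10 higher and 1 lower alone). Mzb1, a chaperone of antibody secretion, rose by 4.19 ± 0.94. Treated replicate 2 had a B cell mean of 9.84 against 5.15 to 7.09 in the other 5, and without it the B cell list was at 1.13 and the plasma cell list at 1.63, neither called by fry. Cell cycle genes fell by 1.1 ± 0.394 with 18 of 20 (19 alone), and Ccnb1 dropped by 1.95 ± 0.31 (adjusted p = 9.12e-06). The T cell, B cell, plasma cell and cell cycle lists each had adjusted p = 0.4 with an estimated correlation. Erythroid genes rose by 1.83 with 5 of 9 (adjusted p = 0.405 with an estimated correlation), and by 1.22 without that replicate, which fry did not call. Hmga2, a chromatin gene of growing cells, dropped by 3.41 ± 0.62. Rn7s1 and Rn7s2, both 3.69 higher, are near-identical copies, so their values are uncertain. The count was 3671 without the 6 libraries with T11 transcripts, 2269 without untreated replicate 3 and 2 when only these groups set the spread. Without the 6, basal epithelial and claudin genes turned to -2.235 and -1.741 (adjusted p = 0.000798 and 0.00938 by fry). With them fry called neither list. In KPB25L, limma called 0 genes, with 1199 at an unadjusted p under 0.05. Its T cell list was 8.14 ± 1.1 (SD, n = 4) treated and 6.73 ± 1.44 (SD, n = 3) untreated, and Cd8a was at 2.38 ± 1.06 (adjusted p = 0.796). Without untreated replicate 2 of KPB25L the count was 44.

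The response of each T11 derivative was then set against that of T11 itself at 7 days. Relative to T11, the change under therapy in T11-Apobec was higher for 594 genes and lower for 369. Nos2 differed by 6.33 ± 1.14 (adjusted p = 0.000114), Mmp12 by 5.62 ± 1.23 and the chemokine gene Ccl5 by 4.65 ± 1. The CD8 list differed by 2.86 (3 of 14 members, 5 alone), the T cell list by 2.13 (2 of 16, 5 alone) and the cell cycle list by -0.952 (3 of 20, 12 alone), each with adjusted p = 0.255 with an estimated correlation. p53 targets differed by 0.743 (3 of 12, 5 alone, adjusted p = 0.0735 with an estimated correlation), among them Cdkn1a at 2.51 ± 0.63. The count ran from 163 without T11-Apobec treated replicate 1 to 2251 without replicate 2, and 8 of 16 such omissions moved it by over 1.5 times. It lay above that range when only these groups set the spread.

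Relative to T11, the change under therapy in T11-UV at 7 days was higher for 89 genes and lower for 30, and 10 lists differed, all of which held with an estimated correlation. The CD8 list differed by 3.57 ± 1.36 (1 of 14 members, 13 alone, adjusted p = 0.0188 with an estimated correlation). MHC class II presentation differed by 2.83 ± 0.643 (2 of 11, 11 alone, adjusted p = 0.0188 with an estimated correlation). The T cell list differed by 2.34 (0 of 16, 12 alone, adjusted p = 0.0457 with an estimated correlation) and the interferon gamma response by 2.66 (1 of 22, 16 alone). The granzyme gene Gzmk differed by 5.58 ± 1.07 (adjusted p = 0.00303), Itgax, an integrin of dendritic cells, by 3.44 ± 0.67 and Ly6a by 4.07 ± 1.01. Cd8a differed by 3.53 ± 1.39 (adjusted p = 0.262). The count was 13 without T11-UV untreated replicate 3 and 327 without untreated replicate 1, and 12 of 16 omissions moved it by over 1.5 times. It was 1 with the flow cell of the file headers as a term, and the 2 T11-UV arms lay on different flow cells. The median of all genes was -0.123 and became -0.0289 after rescaling.

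After 3 days of therapy in sensitive models, the interferon gamma, MHC class I, chemokine and neutrophil lists were higher on average. The interferon gamma response rose by 1.15 ± 0.484 with 15 of 22 members (19 alone), and Irf1, a transcription factor of that response, rose by 1.13 ± 0.2 (adjusted p = 0.000466). MHC class I presentation rose by 0.816 with 9 of 15 (11 alone), among them the peptide transporter gene Tap2 at 1.25 ± 0.27. Chemokines rose by 1.01 with 8 of 14 (12 alone), and neutrophil genes by 1.02 with 5 of 13 (5 alone), among them the calcium-binding gene S100a8 at 1.69 ± 0.45. These 4 lists had adjusted p = 0.29 with an estimated correlation. In KPB25L-UV the interferon gamma list was at -0.31, MHC class I at -0.46 and the T cell list at -0.99. The T cell list was also lower in T11-Apobec, at -0.42, and higher in KPB25L (1.72) and T11-UV (1.28). Gzmb rose by 2.01 ± 0.54 (adjusted p = 0.0117) and Ifng by 1.97 ± 0.56, each in 3 of 4 models, with KPB25L-UV at -0.81 and -1.41. The CD8 list rose by 1.01 with 4 of 14 (9 alone, adjusted p = 0.338 with an estimated correlation), while Cd8a was at 0.04 ± 0.5 and the T cell list at 0.396 (adjusted p = 0.313).

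Other genes and lists also moved at 3 days in sensitive models. The metallothionein gene Mt2 rose by 1.4 ± 0.33, the iron-binding gene Lcn2 by 1.55 ± 0.54 and the immunoproteasome gene Psmb10 by 1.25 ± 0.26 (adjusted p = 0.00258). Apobec3 rose by 0.34 ± 0.11 (adjusted p = 0.0317). Helper T cell genes rose by 0.653 with 3 of 10, NK genes by 0.935 with 2 of 9 (3 alone) and alternatively activated macrophage genes by 0.933 with 4 of 11 (6 alone, adjusted p = 0.338 with an estimated correlation for each). Mast cell genes rose by 1.02 with 4 of 10 (6 alone) and milk protein genes by 1.6 with 5 of 9 (7 alone), both with adjusted p = 0.29 with an estimated correlation. The casein gene Csn3 rose by 3.56 ± 0.84. Fibroblast genes fell by 0.545 with 2 of 15 (9 alone, adjusted p = 0.485 with an estimated correlation), and the matrix genes Sparc and Postn dropped by 0.7 ± 0.18 and 0.82 ± 0.22. In total 1444 genes were higher and 1442 lower. The count was 272 with the flow cell of the file headers as a term, 184 with that of the labels and 0 when only these groups set the spread, where 6432 had an unadjusted p under 0.05. It was 145 without T11-UV treated replicate 1 and 6576 without treated replicate 2, and 9 of 32 omissions moved it by over 1.5 times.

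In resistant models at 3 days limma called 0 genes, with 461 at an unadjusted p under 0.05, and fry called 0 lists. With the flow cell of the file headers as a term limma did call genes, as given in the part on processing. With camera and an estimated correlation, 6 lists were higher. These were the T cell list (0.808, adjusted p = 0.0481), the CD8 list (0.893, adjusted p = 0.0481), the regulatory T cell list (0.617, adjusted p = 0.0359), the checkpoint list (0.7, adjusted p = 0.0195), the interferon gamma response (0.916, adjusted p = 0.0359) and MHC class I presentation (0.687, adjusted p = 0.0359). Adjusted over the list alone, 12 of 22 interferon gamma genes and 11 of 15 MHC class I genes passed. Ctla4 was at 1.73 ± 0.43 and Cd274 at 1.2 ± 0.39, both with adjusted p = 1. The test of sensitive against resistant models at 3 days called 0 genes in limma, with 1815 at an unadjusted p under 0.05, and 0 lists in fry or camera. In it the interferon gamma response differed by 0.237 (adjusted p = 0.863).

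At end stage no gene list was called in the sensitive models. There the T cell list was at 0.176 and the interferon gamma response at 0.353 (adjusted p = 0.996 and 0.822). Cd8a was at 0.99 ± 0.47 (adjusted p = 0.746). Here 0 genes were higher and 6 lower, with 1354 at an unadjusted p under 0.05, and rescaling gave 1 higher and 6 lower. The count was 1 without T11-UV treated replicate 4 and 14 without KPB25L-UV treated replicate 1, and 6 of 24 omissions moved it by over 1.5 times. It was 12 without the 6 libraries with T11 transcripts. In resistant models MHC class I presentation rose by 0.835 ± 0.295 (0 of 15 members called, 13 alone, adjusted p = 0.0362 by fry and 0.0552 with an estimated correlation). Its mean was 12.82 ± 0.38 (SD, n = 5) in treated and 11.5 ± 0.95 (SD, n = 8) in untreated p53-2336R tumours, and 12.34 ± 0.59 and 11.42 ± 0.49 (SD, n = 5 each) in T11. It was 0.27 higher in p53-2225L, so it was higher in 3 of 3 models. Limma called 0 genes there, with 1241 at an unadjusted p under 0.05, and 5 without p53-2225L untreated replicate 5, as the highest of 4 omissions of 23 that gave any. The test of sensitive against resistant models called 0 genes, with 748 at an unadjusted p under 0.05, and MHC class I differed by -0.356 (adjusted p = 0.971).

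**Figure D4:**
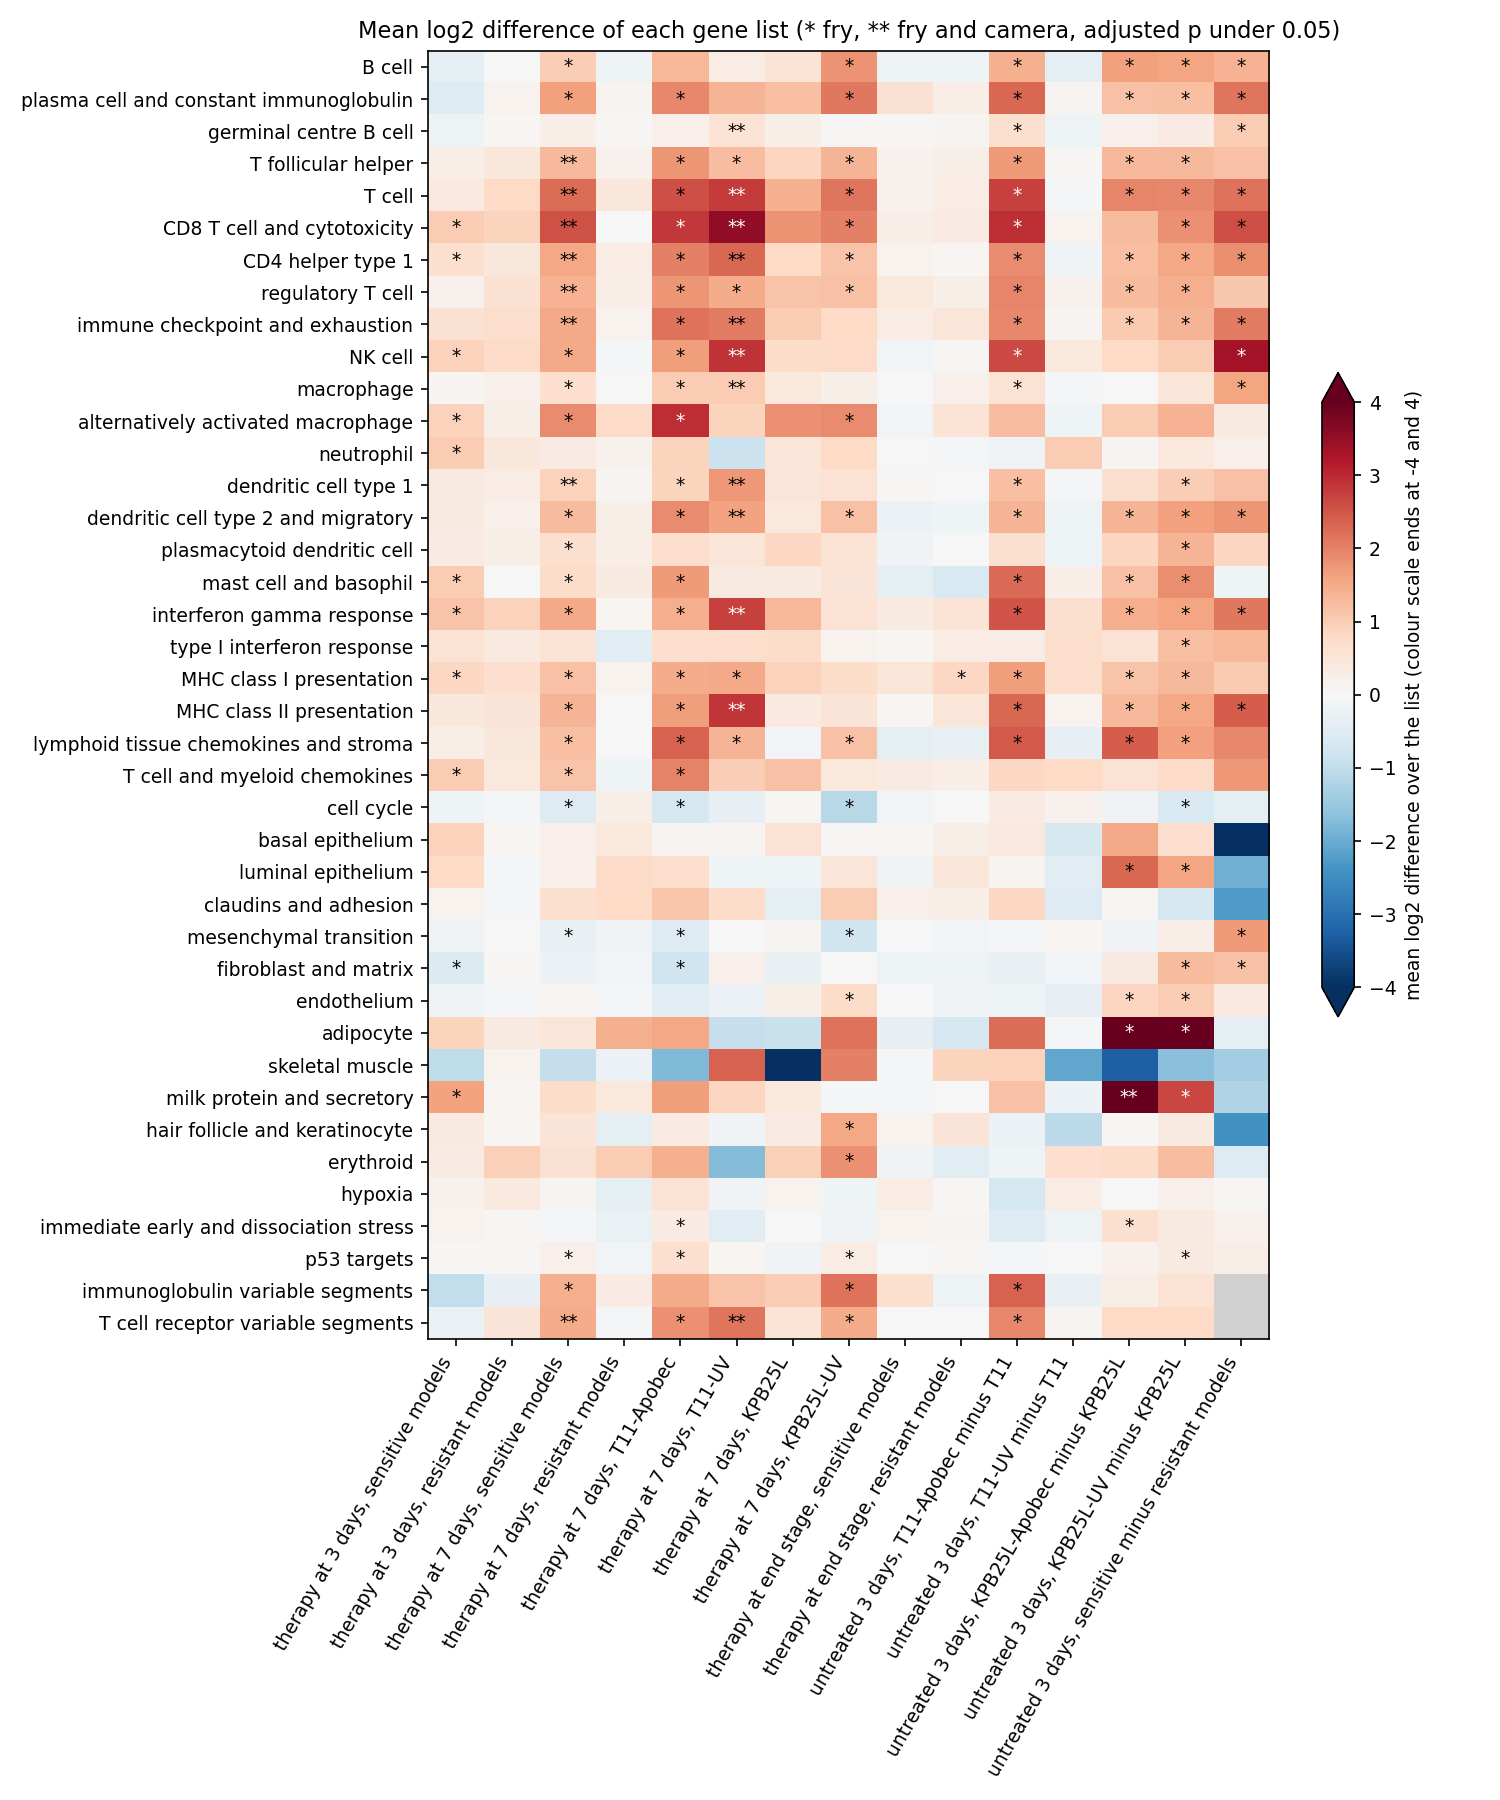
The heat map gives the mean log2 difference of 40 gene lists in 15 comparisons on a scale from -4 to 4, with 1 star for an adjusted p under 0.05 by fry, 2 stars where camera with an estimated correlation also passed, and grey where a list was not tested. The T cell list is at 2.24 at 7 days in sensitive models and at 0.465, not called, in T11.

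Untreated tumours of each derivative were compared with those of its parent at 3 days. For the Apobec derivatives, Apobec3 itself came first. It was 12.13 ± 0.12 in T11-Apobec and 11.17 ± 0.14 in T11 (SD, n = 4 each), a rise of 0.96 ± 0.22 (adjusted p = 0.00293). It lies on chromosome 15 from 79891659 to 79915906 in GRCm38. It was 11.3 ± 0.26 in KPB25L-Apobec and 10.82 ± 0.16 in KPB25L (SD, n = 5 each), a difference of 0.48 ± 0.2 (adjusted p = 0.13). Apobec3 differed by 0.62 ± 0.21 (adjusted p = 0.0367) in KPB25L-UV and by 0.2 ± 0.22 (adjusted p = 1) in T11-UV.

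Untreated T11-Apobec libraries held more immune transcripts than T11 libraries. By the file headers each group lay on a flow cell of its own, so model and flow cell cannot be told apart here. The T cell list was 2.73 ± 0.726 higher with 14 of 16 members (15 alone, adjusted p = 0.0614 with an estimated correlation) and the CD8 list 2.96 ± 0.741 higher with 9 of 14 (14 alone, adjusted p = 0.0614). Cd8a was 8.56 ± 1.11 in T11-Apobec and 4.86 ± 1.23 in T11 (SD, n = 4 each). The interferon gamma response was 2.52 higher with 18 of 22 (22 alone, adjusted p = 0.0675 with an estimated correlation), and MHC class II presentation 2.3 higher with 10 of 11 (11 alone, adjusted p = 0.0614). The chemokine genes Ccl8 and Cxcl9 were 3.79 ± 0.93 and 3.81 ± 1.15 higher. The mast cell list was 2.25 higher with 5 of 10 (6 alone, adjusted p = 0.163 with an estimated correlation), and the plasma cell list 2.3 higher with 4 of 16 (7 alone, adjusted p = 0.195). T11-Apobec replicate 4 had a B cell mean of 9.58 against 4.09 to 4.73 in the other 3. Without it the plasma cell list was at 1.67 and the B cell list at 0.115 instead of 1.41, neither called by fry, while the T cell list was at 2.6 and still called. Igf2, a growth factor gene, was lower at -3.88 ± 0.79, and so was Sfrp2, a modulator of Wnt signalling, at -3.48 ± 0.83. In total 827 genes were higher and 320 lower, and 639 and 516 after rescaling. The count was 11 with the flow cell of the file headers as a term, 101 with that of the labels and 555 without T11-Apobec replicate 3, and 6 of 8 omissions moved it by over 1.5 times.

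Untreated T11-UV tumours differed from T11 tumours in 55 genes, 10 higher and 45 lower, and in 0 lists by fry or camera. Each group lay on a flow cell of its own by the file headers, so model and flow cell cannot be told apart here either. With that flow cell as a term the count was 213, and Hic1, S1pr3 and Serpine2, which were lower, turned to 2.35, 3.63 and 1.36. None of these turned values was called (adjusted p = 0.322, 0.121 and 0.615 by limma). Sema6a, an axon guidance gene, dropped by 2.47 ± 0.35 (adjusted p = 8.28e-07). Pdk3, a kinase gene of glucose oxidation, was 0.76 ± 0.18 higher. T cell genes were at -0.038 and Cd8a at 0.51 ± 0.98 (adjusted p = 1). The count was 93 without the 6 libraries, which shared the spread, and 25 without T11-UV replicate 4, and 7 of 8 omissions moved it by over 1.5 times.

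Untreated KPB25L-Apobec tumours held more milk and fat transcripts than KPB25L tumours, and more T cell transcripts. Milk protein genes were 5.64 ± 3.4 higher with 8 of 9 members (adjusted p = 0.00301 with an estimated correlation). The casein gene Csn3 was 10.48 ± 2.52 in KPB25L-Apobec and 0.56 ± 0.83 in KPB25L (SD, n = 5 each), and Csn1s1 differed by 9.43 ± 1.23. Adipocyte genes were 4.88 ± 1.66 higher with 12 of 13 (adjusted p = 0.101 with an estimated correlation), and the fatty acid carrier gene Fabp4 was 3.47 ± 0.84 higher. Lymphoid tissue genes were 2.42 higher with 5 of 12 (9 alone, adjusted p = 0.101 with an estimated correlation), and the T cell list 1.97 higher with 7 of 16 (16 alone, adjusted p = 0.187). KPB25L-Apobec replicate 3 had a T cell mean of 10.46 against 7.57 to 8.44 in the other 4 and a B cell mean of 10.65 against 4.41 to 6.34. Without it the T cell list was at 1.5 and the lymphoid tissue list at 1.83, both called by fry. The B cell list, at 1.64 with it (adjusted p = 0.0178 by fry), was at 0.53 without it (adjusted p = 0.455). Fry then also no longer called the plasma cell (1.18 with it and 0.778 without) and T follicular helper lists (1.3 and 1.01). The same held for the checkpoint (1.05 and 0.978), mast cell (1.18 and 1.22), interferon gamma (1.45 and 1.53) and MHC class II lists (1.31 and 1.17), whose means moved little. Luminal epithelial genes were 2.31 higher with 4 of 13 (8 alone, adjusted p = 0.194 with an estimated correlation), endothelial genes 0.855 with 5 of 12 (7 alone, adjusted p = 0.201) and immediate early genes, which also mark stress of handling, 0.633 with 2 of 14 (5 alone, adjusted p = 0.194). Pcdhga8 was 5.67 ± 0.94 higher, but its gene cluster shares exons, so its value is uncertain. In total 573 genes were higher and 222 lower, and 573 and 371 after rescaling. By the file headers only 2 libraries of each group shared a flow cell. The count was 76 with the flow cell of the file headers as a term and 6 with that of the labels, and 4 when only these groups set the spread. It was 146 without KPB25L replicate 1 and 1701 without replicate 5, and 8 of 10 omissions moved it by over 1.5 times.

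Untreated KPB25L-UV tumours differed from KPB25L tumours in 2432 genes, 1757 higher and 675 lower, and in 2109 without the 6 libraries with T11 transcripts. By the file headers the groups shared 0 flow cells, so model and flow cell cannot be told apart here. The T cell list was 1.93 ± 0.535 higher with 8 of 16 members (16 alone) and adipocyte genes 4.53 ± 1.44 higher with 11 of 13 (12 alone). MHC class I presentation was 1.3 higher with 6 of 15 (14 alone) and the fibroblast list 1.27 higher with 6 of 15 (9 alone). Each had adjusted p = 0.306 with an estimated correlation. Pparg and Cidea, genes of fat cells that were higher here, turned to -0.17 and -2.43 with the flow cell of the labels as a term. Cidea turned to -3.36 with the flow cell of the file headers. None of these turned values was called (adjusted p = 0.984, 0.886 and 0.439 by limma). The chemokine receptor gene Xcr1 was 3.24 ± 0.66 higher and Cd8a 2.95 ± 0.93 higher (adjusted p = 0.0253). The cell cycle list fell by 0.63 with 6 of 20 (13 alone, adjusted p = 0.306 with an estimated correlation). The ribosomal pseudogenes Rpl9-ps4 and Rpl27-ps3 were at -2.02 ± 0.58 and -1.83 ± 0.37, share reads with their parent genes and are uncertain, and with the flow cell of the labels as a term they were at 0.19 and 0.2. The count was 22 with the flow cell of the file headers as a term, 3 with that of the labels, 207 when only these groups set the spread and 326 without KPB25L-UV replicate 2. It was 1243, 1470 and 1596 without KPB25L replicates 1, 3 and 4. After rescaling 1595 were higher and 1202 lower.

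Model means of untreated tumours at 3 days were compared between 5 sensitive and 7 resistant models. The lists of NK genes (3.32 ± 0.882, 9 of 9 alone), CD8 and cytotoxicity (2.57 ± 0.803, 12 of 13 alone), MHC class II presentation (2.42, 10 of 11 alone), T cell genes (2.19, 12 of 16 alone) and interferon gamma response (2.12, 16 of 22 alone) were higher in the sensitive class. So were the mesenchymal list (1.7, 11 of 14 alone) and the fibroblast list (1.18, 9 of 15 alone). In all 14 lists were higher by fry, each with adjusted p = 0.295 with an estimated correlation and 0 members called. Cd8a was 7.13 ± 1.58 (SD, n = 5) in sensitive and 4.03 ± 1.24 (SD, n = 7) in resistant models (adjusted p = 0.0604). Limma called 0 of 17920 genes, with 3679 at an unadjusted p under 0.05. The models of 1 parental line are not independent, and 3 of the 5 sensitive models were of the KPB25L line. No flow cell term was fitted for the classes. By the file headers, untreated T11 did not share a flow cell with T11-Apobec or T11-UV, nor KPB25L with KPB25L-UV. Class and flow cell were therefore not told apart. On the resistant side, p53-2153F replicates 1 and 2 held an estimated 3.47 and 7.92 M reads. The NK list members Klra4 and Klrc1 were at 931.8 and 91.6 in the culture KPB-25L-CellLine-VALIDATION and listed at 0 in the T11 cultures, so NK cells and tumour cells were not told apart by that list. Klra4 was also present in FVB glands and not in BALB/c glands, so host strain was not told apart by it either. The count was 2245 without T11, 74 without T11-UV, 1 without T11-Apobec and 2104 in a fit of single tumours with the model as a random effect.

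End-stage tumours of 4 models whose response the labels class as unknown were compared with 9 normal mammary glands, 5 of BALB/c and 4 of FVB mice, weighted equally by strain. Cell cycle genes were higher in KPB-Primary (3.59, 20 of 20 members), C3-TAG (4.25, 20 of 20), PyMT (2.73, 20 of 20) and ILC-Pik3Ca/Cdh1Null tumours (0.989, 17 of 20), with adjusted p = 0.0953, 0.217, 0.0763 and 0.582 with an estimated correlation. The mitotic kinase gene Plk1 was 4.15 ± 0.22 higher in KPB-Primary and 3.52 ± 0.32 in PyMT tumours. Adipocyte genes also fell in all 4, at -8.85, -8.06, -9.26 and -5.79 with 13 of 13 members each, with adjusted p = 0.103, 0.218, 0.0902 and 0.441 with an estimated correlation. Lipe, which breaks down stored fat, dropped by 5.66 ± 0.29 in KPB-Primary. B cell genes were lower than in glands in all 4, at -6.62, -6.9, -8.22 and -3.79 with 15 of 15 members each (adjusted p = 0.103, 0.217, 0.0571 and 0.441 with an estimated correlation). Single glands had B cell means of 7.92 to 14.29 log2, so the reference itself varied.

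Other lists also differed between these tumours and glands. Claudin genes were higher in KPB-Primary (2.11, 13 of 14), C3-TAG (2.78, 14 of 14), PyMT (2.99, 14 of 14) and ILC (1.53, 11 of 14). Basal epithelial genes were higher in KPB-Primary (3.52, 12 of 13) and ILC (3.03, 10 of 13). Milk protein genes were higher in PyMT (2.8, 7 higher and 1 lower of 11), with the whey protein gene Wap at 10.15 ± 1.12. ILC tumours had higher macrophage genes (1.6, 10 of 13, 11 alone), with the complement gene C1qb at 2.49 ± 0.28. Type I interferon genes were higher in C3-TAG (1.98, 15 of 18, 16 alone), PyMT (2.07, 14 of 18) and ILC (1.22, 8 of 18). With camera and an estimated correlation, 0 lists were called in any of the 4 comparisons, with adjusted p = 0.119 to 0.753 for the lists of this paragraph. Limma called 13512, 13688, 9916 and 8789 genes in KPB-Primary, C3-TAG, PyMT and ILC. The median of all genes in KPB-Primary was 0.156 and became 0.0199 after rescaling. PyMT and ILC tumours stood in another part of the joined table than the glands.

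The 6 cultured lines had 1 library each, so no test was made and values are given as signal. T-11-CellLine-VALIDATION and KPB-25L-CellLine-VALIDATION were taken as the parents, by name, which their labels do not state. Apobec3 was 3697.11 in T11_EF1A_APOBEC_CELL_LINE, 743.52 in T11_V5_CELL_LINE and 507.36 in T-11-CellLine-VALIDATION. It was 925.72 in KPB_EF1A_APOBEC_CELL_LINE, 760.18 in KPB_25L_V1_5_CELL_LINE and 675.99 in KPB-25L-CellLine-VALIDATION. By the file headers the 6 lines lay on 2 flow cells, and no account was taken of that. In T11_EF1A_APOBEC_CELL_LINE the cell cycle list had a median of 2.04 log2 against the parent, at percentile 100 of 10000 random lists, and Birc5 was 3851.1 against 521.0. That list was also at percentile 100 in KPB_25L_V1_5_CELL_LINE (1.34) and KPB_EF1A_APOBEC_CELL_LINE (0.89), and at -0.13 in T11_V5_CELL_LINE. In T11_V5_CELL_LINE the type I interferon list had a median of 1.4 at percentile 100, and Irf7 was 391.7 against 16.6. In KPB_25L_V1_5_CELL_LINE and KPB_EF1A_APOBEC_CELL_LINE the interferon gamma list had a median of -1.84 each. Gbp6 was 2.5 and 1.4 against 33.0 in the parent, and Tap1 was 64.9 against 745.7 in KPB_25L_V1_5_CELL_LINE. Cd8a, Ifng and Ms4a1 were listed at 0 in all 6 lines. Over 1 log2 from their parent lay 2404 genes in T11_V5_CELL_LINE, 4617 in T11_EF1A_APOBEC_CELL_LINE, 5211 in KPB_25L_V1_5_CELL_LINE and 4358 in KPB_EF1A_APOBEC_CELL_LINE, of 15407.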

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

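The tests of line markers, strain transcripts, flow cells, endothelial genes and table parts in this part were chosen after the result was seen. The predictions for depth and tumour cell content were written before. The read covariate and the T11 markers that they used were chosen after the data were seen. In 43 groups of 4 to 10 libraries, 5 measures were searched for a library far from the rest of its group by Dixon's criterion, which marks about 1 in 20 groups by chance. The numbers marked were 3 for reads, 1 for genes above 0, 5 for the T cell list, 7 for the B cell list and 3 for T11 markers.

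The first pattern weighed was the 6 libraries labelled KPB25L-UV that held T11 transcripts. The most distant, untreated end-stage replicate 2, had a T11 marker mean of 8.35 against 2.88 in the nearest of its group. A swap with T11-labelled tumours would need a partner, and 0 of the 74 T11-labelled libraries had more KPB25L than T11 markers. In the 4 libraries dominated by T11 markers the lowest value of Gvin1, which was at 2234.61 to 8496.86 in FVB glands and 0 to 36.39 in BALB/c glands, was 1048.83, above the highest of 281.79 in T11-labelled libraries, which argues against BALB/c hosts. Gvin1 is also among the 50 KPB25L markers, at 52.33 to 329.34 in the KPB cultures and 0 in the T11 cultures, so it is not a transcript of host cells alone. Ang5, the 1 transcript of FVB glands alone that was at 0 in all 6 cultures, was at 0.0, 1.04, 0.0 and 3.41 log2 in these 4, and at 0.0 in all 74 T11-labelled libraries. A candidate explanation that remains is T11 line cells grown in FVB mice, given a median Gvin1 of 6525 in these 4, while the culture KPB_25L_V1_5_CELL_LINE, whose name the source labels of KPB25L-UV tumours carry, had a T11 marker mean of 0.96 against 0.79 and 1.0 in the other KPB cultures. The other 2 of the 6 libraries held both marker sets, and no explanation for these was weighed. No biological explanation was tested.

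The second pattern weighed was the large response of T11-Apobec at 7 days. Both arms lay on 1 flow cell, and 6710 genes were called with estimated reads as a covariate, so neither flow cell nor depth accounts for it. T11 markers had a median difference of -0.692, at percentile 0.03 of 10000 random lists, so treated tumours may have held fewer tumour cells. That alone would raise other cell types alike, but endothelial genes were at -0.409 (SE 0.21, n = 12 genes) and T cell genes at 2.59 (SE 0.15, n = 16 genes). These SEs are over genes of the same tumours and do not measure spread between mice. Whether therapy changed the endothelium itself was not tested. A response to therapy stays open as a hypothesis.

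The third pattern weighed was the difference of PyMT and ILC tumours from normal glands. These tumours and the glands shared 0 parts of the joined table, so part and tissue cannot be told apart there. Within the 4 groups that lay in both parts, 28 genes of 20848 differed between parts, with 2596 at an unadjusted p under 0.05 and a median shift of 0.0973 over all genes.

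Among T cell list means, T11-UV untreated replicate 1 at 7 days was at 7.73 against 6.18 in the nearest of its group, and its T11 marker mean was 8.08 against 8.68. The T cell mean was 9.29 against 5.76 in T11-UV untreated end-stage replicate 2, 7.75 against 5.77 in p53-2336R treated replicate 4 at 3 days and 5.49 against 6.56 in p53-2153F untreated replicate 1 at 3 days. BALB/c gland replicate 1 had a T cell mean of 13.16 against 11.38 and a B cell mean of 14.29 against 11.43.

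Among B cell list means, T11-Apobec untreated replicate 4 at 3 days was at 9.58 against 4.73, and T11-Apobec treated replicate 2 at 3 days was at 6.25 against 4.06. T11-UV untreated end-stage replicate 2 was at 8.51 against 4.24, and T11 untreated end-stage replicate 5 at 7.59 against 3.86. KPB25L-UV untreated replicate 2 at 3 days was at 8.06 against 5.65. Replicate 3 of untreated p53-2224L at 3 days was at 3.78 against 3.91, and its T11 marker mean was 4.25 against 4.98.

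The depth of p53-2336R treated end-stage replicate 5 was 95.33 M estimated reads against 46.14 M in the nearest of its group. Values of 56.03 against 44.14 M were found in KPB25L treated replicate 1 at 3 days and 59.32 against 40.78 M in KPB25L-UV treated end-stage replicate 3. KPB25L-UV untreated end-stage replicate 6 had 22379 genes above 0 against 21512.

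The tests of a difference between responses at 7 days also stood out. The response of sensitive models differed from that of T11 in 1 gene, that of T11-Apobec in 963 genes and that of T11-UV in 119 genes.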

How the results depend on the processing

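The header flow cell, read covariate, 1-flow-cell and 6-library settings below, with the table part, were chosen after seeing the data, and the others were planned. Of 245 counts under other settings, 169 stayed within 1.5 times. Counts of 0 that stayed at 0 are among these, so the share overstates how steady the other counts were. The 7-day count of sensitive models, 7659, did so under each setting run and each omission run (6336 to 8539), which covered groups of up to 5 libraries. Among named genes 1172 of 1202 kept direction and call with a pseudocount of 10, 1059 of 1186 with array weights, 845 of 1094 with the label flow cell and 492 of 840 with the header flow cell. Where a count below changed, the cause was not tested. A fit of fewer groups has fewer degrees of freedom and a spread of its own, and a setting without a filter tests more genes. No paired analysis was possible because the labels number each mouse on its own and no number is shared by a treated and an untreated group. Leaving out mice DH1012 to DH1015 leaves a treated arm with no library, so comparisons that use this arm could not be fitted as defined. The 7-day fit of sensitive models with both arms on 1 flow cell held KPB25L, KPB25L-UV and T11-Apobec, and so no T11-UV.

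The array weights ran from 9.25e-17 to 18 in the tumour fit, where the iteration stopped before it converged, so their counts are uncertain. They gave 88 calls at 7 days in resistant models, 3970 for sensitive minus resistant, 10504 in T11-Apobec, 7871 in T11-UV, 3 in KPB25L and 1009 in KPB25L-UV. For the responses against that of T11 they gave 8175 for T11-Apobec and 6177 for T11-UV. At 3 days they gave 11655, 19 and 8392 in sensitive models, resistant models and their difference, and at end stage 327, 434 and 42. In untreated tumours they gave 8324 for T11-Apobec, 2615 for T11-UV, 4499 for KPB25L-Apobec and 5023 for KPB25L-UV against their parents, and 13667 for ILC against glands.

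With only the groups of a comparison, calls were 0 for sensitive minus resistant at 7 days (1584 at an unadjusted p under 0.05), 442 in T11-UV, 2 in KPB25L-UV, 6352 for T11-Apobec minus T11 and 670 for T11-UV minus T11. They were 0 in sensitive models at 3 days, and 3 in sensitive and 3 in resistant models at end stage. In untreated tumours they were 6968 for T11-Apobec, 934 for T11-UV, 4 for KPB25L-Apobec and 207 for KPB25L-UV. The main counts were 1147, 55, 795 and 2432, so the first 2 rose and the last 2 fell. Fewer degrees of freedom cannot account for a rise. These fits also took the spread from the compared groups alone. In these untreated groups the SD of the T cell list was 0.79 in T11, 0.56 in T11-Apobec and 0.13 in T11-UV. It was 0.88 in KPB25L and 1.01 in KPB25L-UV. A pooled spread may therefore be too narrow for some groups and too wide for others.

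With the flow cell of the labels, calls were 19 for sensitive minus resistant at 7 days, 1 in KPB25L, 217 for T11-UV minus T11, 184 in sensitive models at 3 days and 1 in resistant models at end stage. In untreated tumours they were 101 for T11-Apobec, 6 for KPB25L-Apobec and 3 for KPB25L-UV, and 5706 for KPB-Primary against glands. This setting turned Cd37 to -0.29 in untreated T11-Apobec. In untreated KPB25L-UV it turned Rpl9-ps4 to 0.19, Rpl27-ps3 to 0.2, Cd37 to -0.41, Pparg to -0.17, Cidea to -2.43 and Csn3 to -0.42. None of the genes turned by this setting was called with it (adjusted p = 0.886 to 0.984 by limma).

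With the flow cell of the file headers, calls were 36 for sensitive minus resistant at 7 days, 8 in T11-UV, 1 in KPB25L and 1 for T11-UV minus T11. They were 272 in sensitive and 114 in resistant models at 3 days and 1 in resistant models at end stage. In untreated tumours they were 11 for T11-Apobec, 213 for T11-UV, 76 for KPB25L-Apobec and 22 for KPB25L-UV. Hbb-bs turned to 0.61 in T11-UV at 7 days. In untreated T11-UV, Hic1 turned to 2.35, S1pr3 to 3.63 and Serpine2 to 1.36. Cidea turned to -0.04 in untreated KPB25L-Apobec. In untreated KPB25L-UV, Rpl9-ps4 turned to 0.07, Tnfrsf13c to -0.17 and Cidea to -3.36. None of the genes turned by this setting was called with it (adjusted p = 0.121 to 0.994 by limma).

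With estimated reads as a covariate, calls were 1675 for T11-Apobec minus T11, 199 for T11-UV minus T11, 1223 for untreated KPB25L-Apobec and 1 in resistant models at end stage. With only models whose arms shared 1 flow cell, sensitive minus resistant at 7 days gave 6. Median-of-ratios rescaling gave 186 for T11-UV minus T11. A pseudocount of 10 gave 3 for sensitive minus resistant at 7 days, 190 for T11-UV minus T11, 1 in resistant models at end stage and 1325 genes past 1 log2 in T11_V5_CELL_LINE.

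Without a filter on the mean, calls were 8 in resistant models and 14 for sensitive minus resistant at 7 days, 26 in KPB25L, 9 and 1 in resistant models and sensitive minus resistant at 3 days, 18 and 3 for the same at end stage, and 84 in untreated T11-UV. Without the 6 KPB25L-UV libraries, calls were 5 for sensitive minus resistant at 7 days, 1 for it at 3 days, 12 in sensitive models at end stage, 231 for T11-UV minus T11 and 93 in untreated T11-UV. In KPB25L-UV at 7 days basal epithelial genes turned to -2.235 and claudins to -1.741 (adjusted p = 0.000798 and 0.00938 by fry). With the 6 libraries fry called neither list there. The class comparison gave 2104 with single tumours and the model as a random effect (consensus correlation 0.711). Fry made 317 list calls and camera with an estimated correlation made 37, of which 6 were of lists that fry did not call. The plasmacytoid dendritic cell list in C3-TAG had a mean of -1.014 and a median of 0.222.

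Omissions of 1 library were run in groups of up to 5 libraries. They gave 0 to 27 for sensitive minus resistant at 7 days, 0 to 0 in resistant models, 2605 to 7143 in T11-Apobec, 793 to 2192 in T11-UV, 0 to 44 in KPB25L and 2269 to 4161 in KPB25L-UV, where the 4 untreated libraries were omitted and the 6 treated were not. They gave 163 to 2251 for T11-Apobec minus T11 and 13 to 327 for T11-UV minus T11. At 3 days they gave 145 to 6576 in sensitive models, 0 to 0 in resistant models and 0 to 1 for the difference, and at end stage 1 to 14, 0 to 5 and 0 to 0. In untreated tumours they gave 555 to 839 for T11-Apobec, 25 to 37 for T11-UV, 146 to 1701 for KPB25L-Apobec and 326 to 3601 for KPB25L-UV. Added after seeing the data, an omission of KPB25L-UV treated replicate 2 at 7 days left the B cell list there at 1.13 (adjusted p = 0.113 by fry), the plasma cell list at 1.63 and the erythroid list at 1.22, none of them called. An omission of KPB25L-Apobec untreated replicate 3 left the T cell list at 1.5 (adjusted p = 0.0277 by fry). An omission of T11-Apobec untreated replicate 4 at 3 days left the plasma cell list at 1.67 (adjusted p = 0.0799 by fry). Omitting 1 model gave 0 to 2245 for the classes. Against glands they gave 12836 to 13516 in KPB-Primary, 13214 to 13747 in C3-TAG, 8969 to 10216 in PyMT and 8239 to 8773 in ILC. In the simulated values a change of 1 log2 was recovered for 36% of genes in T11 at 7 days and 17% in KPB25L. The noise there had 1 spread per gene for all groups, so these shares do not speak of the depth or spread of either model.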

Other observations

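The counts of splits were set out before the results were seen, and the repeat pair and the lists and genes singled out in this part were chosen after. In KPB25L tumours at 7 days skeletal muscle genes were at -6.42 in treated against untreated libraries (adjusted p = 0.162 by fry). In KPB25L-UV at 7 days the hair follicle list rose by 1.55 with 2 of 9 members (adjusted p = 0.405 with an estimated correlation) and the endothelium list by 0.729 with 3 of 12 (6 alone, adjusted p = 0.408). Without treated replicate 2 they were at 1.52 and 0.63, and fry called neither. Immediate early genes rose in T11-Apobec at 7 days by 0.338 on average with 4 of 14 members higher and 1 lower, and the stress gene Atf3 among them rose by 3.03 ± 0.52 (adjusted p = 0.476 for the list with an estimated correlation).

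No test between single models was made at 3 days. The mean difference of the interferon gamma list under therapy was 1.93 in KPB25L, 1.58 in T11-UV, 1.41 in T11-Apobec, 1.34 in T11, 0.92 in p53-2336R and 0.48 in p53-2225L, and -0.31 in KPB25L-UV, with SDs between tumours of 1 group of up to 2.04. In C3-TAG tumours against glands, hypoxia genes were 0.966 higher with 7 of 14 members higher and 2 lower (adjusted p = 0.828 with an estimated correlation), with Car9, a carbonic anhydrase gene, at 4.29 ± 0.48.

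The 2 libraries of 1 KPB25L mouse differed with an SD of 0.648 across genes, against 0.927 to 1.55 between mice.

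Other splits of the same samples into groups of the same sizes were counted for each comparison, the real split included. With at most 100 splits each and no adjustment over the comparisons, these counts cannot exclude chance. At 7 days in sensitive models 1 of 100 splits, the real one, gave as many calls as 7659, with 4063 in the highest other. Few splits also reached the real count for sensitive models at 3 days (1 of 100, 2886, highest other 588) and T11-Apobec at 7 days (1 of 35, 6120, highest other 2197). So it was for T11-Apobec minus T11 (2 of 100, 963, highest other 1074) and T11-UV minus T11 (1 of 100, 119, highest other 56). The same held against their parents for untreated T11-Apobec (1 of 35, 1147, highest other 1) and T11-UV (1 of 35, 55, highest other 0). It also held for KPB25L-Apobec (3 of 100, 795, highest other 1022) and KPB25L-UV (2 of 100, 2432, highest other 3471). In T11-Apobec minus T11, KPB25L-Apobec and KPB25L-UV another split called more than the real one, so a structure among these libraries beside the model is left open. The real splits of untreated T11-Apobec, T11-UV and KPB25L-UV also followed the flow cell, so model and flow cell cannot be told apart there, and with the header flow cell as a term the counts were 11, 213 and 22. In T11-UV minus T11 the 2 T11-UV arms lay on different flow cells, so therapy and flow cell cannot be told apart. With the header flow cell as a term that count was 1. For sensitive minus resistant at 7 days 3 of 100 splits gave 1 or more, with 1 in the highest other, and for sensitive models at end stage 3 of 100 gave 6 or more, with 20 in the highest other.

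Chance was not made unlikely for T11-UV at 7 days, where 6 of 35 splits gave as many as 1555 and the highest other gave 4941. Nor was it for KPB25L-UV, where 8 of 100 gave as many as 4048 and the highest other gave 6499. Of the 10 KPB25L-UV libraries 4 held T11 transcripts, and splits that follow these mix such transcripts with the arm, so this count does not speak of therapy alone. The highest other split of T11-UV called several times the real count, which points to a structure among these libraries other than therapy. In KPB25L at 7 days a split other than the real one called 1095 genes, against 0 in the real one, which also points to such a structure. A real count of 0 is reached by every split, so the splits say nothing on chance there. That was so for 35 of 35 splits in KPB25L and 35 of 35 in T11 at 7 days (highest other 0), and for 100 of 100 in resistant models at 3 days (2), sensitive minus resistant at 3 days (1), resistant models at end stage (13), sensitive minus resistant at end stage (4) and the class comparison (111). Against glands 1 of 100 splits gave as many as in KPB-Primary (13512, highest other 3549), C3-TAG (13688, highest other 9154), PyMT (9916, highest other 4917) and ILC (8789, highest other 6343).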
